A study of Homo sapiens with 2 samples.

How the data were processed

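Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in HCT116, a human colon cancer cell line. The samples were 1 library of wild-type cells (WT) and 1 library of cells with the K206R form of PKM2, the M2 isoform of pyruvate kinase, in which a lysine is replaced by arginine. How the mutant was made is not given in the sources used here. The labels' extraction protocol describes lysis, transposition and amplification only, while the series' design text also names an antibody against acetylated histone H3; the peak tables were treated as transposition data, and which of these statements is complete is left open. The protocol also mentions clinical material, which was not analysed here.

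Each library came with 1 deposited peak table, so peaks were called per library and not on pooled samples. Per the submitters' processing notes the genome build was hg38, and DiffBind and deepTools were used, with no role given. The aligner, the peak caller, the duplicate and mitochondrial filters and any shift of reads for the transposase are not given in the sources used here. Per the file headers, each peak has its position, its length, its summit and the deposited pileup, a coverage signal at the summit in whole numbers. Per the file headers, each peak also has the caller's −log10 of the p-value and of the q-value, and a fold enrichment. The fold was taken as the ratio of the pileup to the caller's background, with 1 added to each. These scores and folds are the authors' own values for each peak, and they were used to describe, rank or filter peaks within 1 list. The exception is the background implied by fold and pileup, which was compared between the libraries as a measure of depth and used, with the p limit, to thin the WT library. The smallest deposited −log10 q-value was 1.31 in both tables, which corresponds to a largest q of 0.0486 in the WT table and 0.0487 in the K206R table. Peak lengths in the deposited tables started at 275 bp in WT and 276 bp in K206R. Per the file headers the authors also gave each peak an annotation class, the nearest transcript's gene and the distance to its transcription start; the promoter class reached 3 kb from a start. The deposited p-value equalled the Poisson tail of the pileup over a background implied by the fold, with a largest difference of 0.000354 on the −log10 scale over 57422 WT peaks and of 0.000172 over 49092 K206R peaks.

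The total number of reads per library is not given in the sources used here. The lowest background implied by the deposited fold and pileup was therefore taken as a measure of relative depth, since such a floor scales with the number and length of the fragments. It was 2.10 in WT and 1.65 in K206R, a ratio of 1.27. The median summit pileup was 30 in WT and 25 in K206R. The pileups printed here are as deposited and not scaled to depth.

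Peaks of the 2 samples were called shared when they overlapped by at least 1 bp, computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; bedtools 2.31.1 gave 0 differing calls. Overlapping peaks of both libraries were merged into regions for counts over genes. Shares carry 95% Wilson intervals and ratios of pileups at single regions carry 95% Clopper-Pearson intervals. The median pileup ratio and the difference in log2 ratio between promoters and other regions carry 95% bootstrap intervals. These resample peaks within these 2 libraries, with 1000 and 200 draws. The Wilson and Clopper-Pearson intervals cover counting error only. None of the intervals contains the variation between cultures or libraries. With 1 library per genotype there was no replicate check and no test of the genotype, so every difference below is one between these 2 libraries. The gene of a peak is the authors' nearest gene, matched by its identifier to the RefSeq table of GRCh38.p14 for 99.7% of the peaks of each library; that table also gave the positions of FOSL1 and PKM and separated coding from other genes.

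For 16 gene lists with 308 different genes, all of them found in the RefSeq table, the regions annotated to the list were counted as shared, WT only or K206R only. The balance was the number of K206R-only minus WT-only regions as a share of all regions of the list. It was placed among 10000 random lists of the same size matched on the number of regions per gene; 27 genes stand in more than 1 list. The lists were AP-1 and small Maf subunits, AP-1 linked invasion and growth factor genes, vasculogenic mimicry genes, angiogenic factors, epithelial-mesenchymal transition genes, glycolysis and lactate, hypoxia response, Wnt and intestinal stem cell genes, colon epithelial differentiation, super-enhancer machinery and coactivators, lactylation and acylation enzymes, cell cycle, ubiquitously used genes, and endothelial, stromal and immune cell markers. Peak clusters were runs of at least 5 peaks with gaps of up to 12.5 kb, the distance commonly used to stitch super-enhancers; without an acetylation signal they are only clusters of accessible regions.

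The comparisons, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names FOSL1 and PKM, list members with a promoter peak in 1 library only, the 12 coding genes per library whose library-only promoter peak has the highest fold in its own list, the 6 genes with the most library-only regions per library, and up to 4 genes per list with the most library-only regions. Of the list members, those that carry the account of each list are given. Some genes that the rule names are not reported here. Alternatives were a −log10 q of at least 5, equal numbers of peaks per library, a 50% overlap, chromosomes 1 to 22 and X, another promoter window, other stitching settings and a wider window at FOSL1. Alternatives added later thinned the WT library to the K206R depth or left out peaks more than 500 kb from a start, and for pileup ratios left out peaks that were split in 1 library. A search for the AP-1 site was planned and not run, because it needs the genome sequence, which was not used here.

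The steps were tested on simulated data. Of 5000 simulated peaks without a partner, 5000 were found. Of 10 lists of 20 genes with about as many regions removed as kept, 10 lay below the random range. Of 100 lists of 20 unchanged genes, 3 lay outside it. Smaller losses were not simulated, so how often a list with a weaker shift would be found is not known. Thinning gave 99.7% of the number of peaks of a simulated shallower library, and 98.4% when a smallest length was also required. Both simulated libraries were drawn at the WT peaks, so regions missing from the WT list were not simulated. The simulated lengths had the same triangular peak shape that the thinning assumes. The 98.4% therefore does not check that shape on real peaks.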

Results

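The accessible chromatin of HCT116 colon cancer cells was compared between a wild-type PKM2 library and a PKM2 K206R library, with 1 library per genotype. PKM2 is the pyruvate kinase isoform that completes glycolysis in many tumour cells. The series asks how lactylation of PKM2 relates to vasculogenic mimicry, to resistance to bevacizumab and to a super-enhancer at FOSL1, a gene for an AP-1 transcription factor subunit. The WT table listed 57443 peaks with a mean length of 811 bp, covering 46.6 Mb. The K206R table listed 49104 peaks with a mean length of 784 bp, covering 38.5 Mb. There was no replicate of either genotype, and the intervals given cover counting error only.

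FOSL1 lies on chromosome 11 at 65892049 to 65900545 (hg38), and both of its listed peaks were present in both libraries. The peak over its transcription start spanned 65899193 to 65900649 in WT, with a summit pileup of 99, and 65899339 to 65900674 in K206R, with a pileup of 97. A second promoter-class peak, 2 to 3 kb upstream of the start, spanned 65903011 to 65903770 in WT with a pileup of 76 and 65903006 to 65903621 in K206R with a pileup of 56. Within 50 kb of FOSL1 the WT library had 13 peaks and the K206R library 11. Of the 13 WT peaks, 12 overlapped a K206R peak, and all 11 K206R peaks overlapped a WT peak. The exception was a peak at 65851035 to 65851690 with a pileup of 25, in an exon and nearest to CFL1, the gene of the actin-binding protein cofilin. At C11orf68 and DRAP1 the WT library listed 2 peaks, with pileups of 89 and 149, where the K206R library listed 1 with a pileup of 121. Both libraries had a cluster of peaks over FOSL1 that also took in FIBP, CCDC85B, C11orf68 and DRAP1. The cluster held 9 peaks over 45.1 kb in WT and 8 peaks over 44.9 kb in K206R, all of them shared. Raw pileups follow the depth of each library, and the median WT pileup at shared peaks was 1.39 times the K206R pileup, so pileups set side by side do not show a change.

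**Figure D1:**
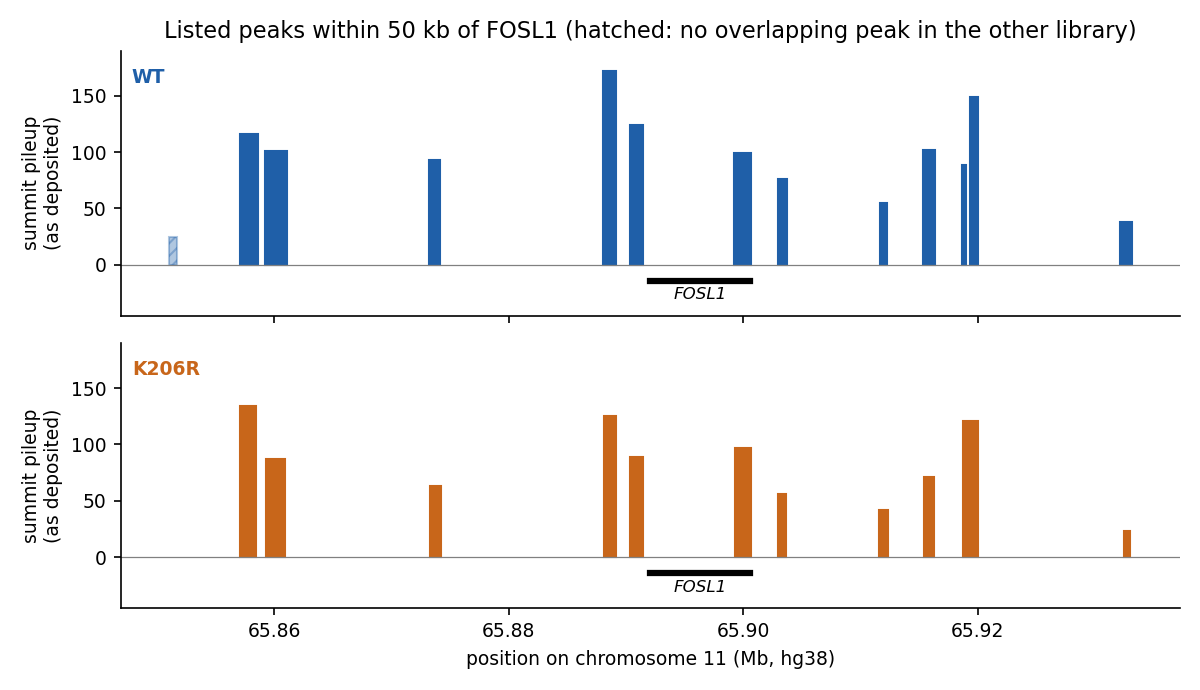
Peaks within 50 kb of FOSL1 on chromosome 11 (hg38, Mb) in the WT library (top) and the K206R library (bottom), each bar as wide as its peak and as high as its deposited summit pileup. The WT library had 13 peaks and the K206R library 11, and the hatched WT peak near CFL1 was the only one without an overlapping peak in the other library.

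PKM, the gene of the mutated enzyme, lies on chromosome 15 at 72199029 to 72231591 and had 3 annotated peaks in WT and 4 in K206R. All 3 WT peaks were shared. The peak over the PKM start spanned 72230791 to 72232044 in WT with a pileup of 219 and 72230212 to 72231944 in K206R with a pileup of 129. The peak at 72226700 to 72227347 in WT, annotated 1 to 2 kb from the start of another PKM transcript, had pileups of 70 and 46, and the one about 5 kb upstream of the PKM start, at 72237123 to 72238073 in WT, had 85 and 58. The additional K206R peak stood at 72199908 to 72200267, near the other end of the gene, with a pileup of 35 and a −log10 q of 7.58. Its annotation as promoter rests on a transcript that starts inside PKM, and the nearest WT peak, at GRAMD2A, was 1.58 kb away. A peak list does not read the mutated codon, so these values do not check the genotype labels.

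Across the genome the strongest accessible regions were listed in both libraries. Of the WT peaks, 44118 (76.8%, 76.5 to 77.1) overlapped a K206R peak, and of the K206R peaks 44287 (90.2%, 89.9 to 90.5) overlapped a WT peak. This left 13325 WT-only and 4817 K206R-only peaks. Merged over both libraries there were 62055 regions, of which 43913 (70.8%) were shared, and the Jaccard index of the covered length was 0.661. With each library's peaks ranked by −log10 q and split into 10 groups of equal size, 99.9% of the WT peaks in the highest group had a partner, against 24.0% in the lowest. In K206R 53.7% of the lowest group had a partner. The median pileup was 14 for WT-only and 40 for shared WT peaks, and 11 for K206R-only and 28 for shared K206R peaks. A −log10 q of at least 20 was reached by 130 WT-only and 9 K206R-only peaks. With the 49104 highest-ranking peaks of each library, 85.1% of the WT and 85.5% of the K206R peaks were shared, which left 7329 and 7112 library-only peaks; lists of equal length bring these numbers close by construction.

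**Figure D2:**
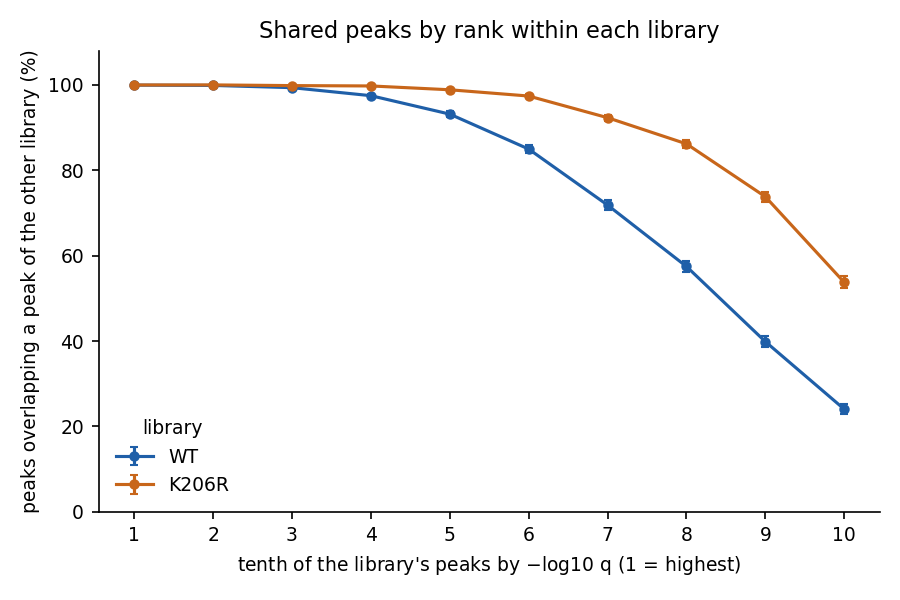
Share of peaks (%) that overlap a peak of the other library, in 10 groups of equal size by −log10 q within each library, for WT and K206R, with 95% Wilson intervals that cover counting error only. The WT share went from 99.9% in the highest group to 24.0% in the lowest, and the K206R share ended at 53.7%.

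Promoters made up the largest class of the shared peaks, and introns and intergenic regions that of the library-only peaks. Of all peaks, 38.7% in WT (38.3 to 39.1) and 42.0% in K206R (41.5 to 42.4) were annotated to promoters. The promoter share was 19.4% in WT-only peaks (18.7 to 20.04) and also 19.4% in K206R-only peaks (18.3 to 20.5). Introns held 38.5% of the WT-only and 38.9% of the K206R-only peaks, and distal intergenic regions 34.9% and 35.7%. Seen from the class, 88.4% of the WT promoter peaks had a partner, against 69.5% of the other WT peaks. In K206R these shares were 95.5% and 86.4%. The intervals of the WT-only and K206R-only sets overlapped for promoters, introns and intergenic regions alike.

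**Figure D3:**
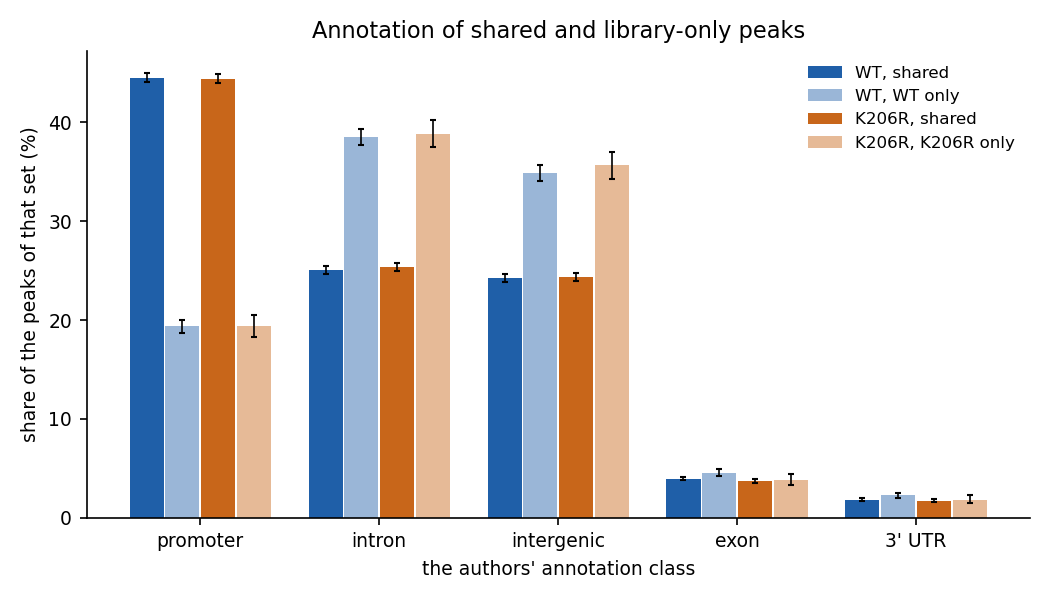
Share (%) of shared and library-only peaks in the authors' annotation classes for WT and K206R, with 95% Wilson intervals that cover counting error only. Promoters held 44.5% of the shared WT peaks and 19.4% of the WT-only peaks, and the K206R sets had nearly the same shares, 44.4% and 19.4%.

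A promoter peak was found for 15885 genes in WT and 15395 in K206R, and 14929 genes had one in both. A promoter peak without an overlapping K206R peak occurred at 2337 genes in WT, and one without an overlapping WT peak at 905 genes in K206R. Most of these genes had another promoter peak in the other library. The other library had no promoter peak annotated to the same gene for 838 genes in WT, 485 of them coding. In K206R this held for 350 genes, 223 of them coding. Peaks annotated to a neighbouring gene were not counted. With equal numbers of peaks per library the counts were 1365 WT-only and 1371 K206R-only genes, which are likewise close by construction.

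The 12 coding genes whose WT-only promoter peak stood highest by fold in the WT list were GRM8, TOP1, BBS4, MEF2C, KNDC1, ARID1B, PPP1R42, SPECC1, APOBEC3G, SERHL2, RTP3 and BUD31. The GRM8 peak, at a glutamate receptor gene on chromosome 7 (127107691 to 127108127), had a fold of 12.3 and a pileup of 37. The peak at TOP1, the gene of DNA topoisomerase I, lay on chromosome 20 (41095115 to 41095578) with a fold of 9.89, and the nearest K206R peak was 41.1 kb away; another TOP1 promoter peak was listed in K206R. At MEF2C, a transcription factor gene, the fold was 9.37, and 3 other MEF2C promoter peaks were listed in K206R. At ARID1B, a subunit of the SWI/SNF chromatin remodelling complex, it was 9.16, with 4 other promoter peaks in K206R. GRM8 and KNDC1 had 1 promoter peak each in K206R and SPECC1 had 2. BBS4, PPP1R42, APOBEC3G, SERHL2, RTP3 and BUD31 had no promoter peak annotated to them in K206R. A peak that the authors gave to a neighbouring gene was not counted, so a K206R peak at the main start of these genes is not excluded. The K206R peak nearest to the BUD31 peak was 5.91 kb away, with a pileup of 132, and was annotated to PDAP1. For BBS4 it was 35.5 kb away, with a pileup of 76, and was annotated to HIGD2B. The 12 WT peaks had pileups of 26 to 42 and lengths of 315 to 541 bp.

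The corresponding 12 genes of the K206R list were BANP, FSIP1, TAFA4, C10orf105, CMTM2, USP17L22, SORCS2, SCAMP2, PCDH19, MAGEA6, AP5Z1 and NRM. BANP, a gene of a nuclear matrix associated protein, had a K206R-only peak on chromosome 16 (87983154 to 87983554) with a fold of 8.28 and a pileup of 21. FSIP1 had a fold of 7.18 and TAFA4 one of 6.80. PCDH19, a protocadherin gene, had a peak over its start on chromosome X (100409912 to 100410509) with a fold of 6.44, and the cancer-testis gene MAGEA6 one with a fold of 6.43. The USP17L22 peak had the highest pileup of the 12, 44. This gene belongs to a tandem family of near-identical copies, so its reads may be hard to assign, which was not tested. BANP, SCAMP2 and AP5Z1 had another promoter peak in WT, and the other 9 genes had none annotated to them. Here too a peak given to a neighbouring gene was not counted, so a WT peak at the main start of these 9 genes is not excluded. The WT peak nearest to the FSIP1 peak was 18.7 kb away, with a pileup of 175, and was annotated to LOC105370941. The folds of the WT and K206R lists are not compared here, since each is relative to the background of its own library.

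The list of AP-1 and small Maf subunits covers the family of FOSL1. Of its 36 regions at 15 genes, 33 (91.7%) were shared, 2 were WT only and 1 was K206R only. With a reciprocal 50% overlap 31 of 38 were shared. A promoter peak was present in both libraries at 13 of the 15 genes. FOS had the only library-only promoter peak of the list, at chromosome 14 (75282481 to 75284073) in WT with a pileup of 58, and it had 2 other promoter peaks in K206R. BATF3 had 1 WT-only region, with a −log10 q of 2.25, while all 6 regions of ATF3 were shared. The balance of the list was −2.78% and stood at percentile 87.0 of the random lists. Genes of invasion and growth factors linked to AP-1 had 81 regions, of which 56 were shared, 20 WT only and 5 K206R only, a balance of −18.5% at percentile 17.1. Of these, CCND1, the cyclin D1 gene, had 5 shared, 3 WT-only and 1 K206R-only region. Its WT-only promoter peak at chromosome 11 (69640649 to 69641424) had a pileup of 95 and lay 1.08 kb from a K206R peak of CCND1 with a pileup of 96. EREG, the gene of the growth factor epiregulin, had 3 shared, 2 WT-only and 1 K206R-only region.

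Genes of vasculogenic mimicry, the formation of vessel-like channels by tumour cells, had 74 regions, of which 49 were shared, 20 WT only and 5 K206R only. Their balance of −20.3% stood at percentile 13.8. With equal numbers of peaks they had 10 WT-only and 9 K206R-only regions, a balance of −1.56% at percentile 42.3. PTK2, the focal adhesion kinase gene, had 8 shared, 4 WT-only and 2 K206R-only regions. CDH5, which encodes VE-cadherin, had 7 shared, 2 WT-only and 1 K206R-only region. The receptor tyrosine kinase gene EPHA2 had 6 shared and 2 WT-only regions, 1 of them a promoter peak at chromosome 1 (16133117 to 16133557) with a pileup of 25. GAL3ST1, a sulfotransferase gene, had 2 WT-only promoter peaks with pileups of 17 and 12 and no promoter peak annotated to it in K206R. Angiogenic factors had 62 shared, 19 WT-only and 8 K206R-only regions, a balance of −12.4% at percentile 57.4. VEGFB, a gene of the growth factor family whose member VEGFA is the target of bevacizumab, had a WT-only promoter peak at chromosome 11 (64234832 to 64235253) with a pileup of 62. The nearest K206R peak was 0.435 kb away and had a pileup of 43. PDGFB had 7 shared and 3 WT-only regions and PDGFC 5 and 3. ANGPT1, the angiopoietin 1 gene, had 2 WT-only and 1 K206R-only region and none shared.

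Genes of the epithelial-mesenchymal transition had 45 shared, 19 WT-only and 10 K206R-only regions, a balance of −12.2% at percentile 58.3. TGFBR2, the type II TGF-beta receptor gene, had 7 shared and 7 WT-only regions, the latter with −log10 q between 1.62 and 5.32. CDH1, the E-cadherin gene, had 6 shared and 3 K206R-only regions, with −log10 q between 1.64 and 4.56. Of the regions annotated to ITGA5, 2 were WT only, 1 was K206R only and none was shared. The WT peak nearest to the K206R-only peak of ITGA5 was 6.22 kb away, with a pileup of 87, and was annotated to GPR84-AS1. A promoter peak of TGFB1 with a pileup of 9 was listed in K206R only. The nearest WT peak was 9.2 kb away, with a pileup of 96, and was annotated to TMEM91. Wnt and intestinal stem cell genes had 62 shared, 21 WT-only and 3 K206R-only regions, a balance of −20.9% at percentile 11.4. SMOC2 had 2 shared and 6 WT-only regions. RNF43, an inhibitor of Wnt receptors, had 9 shared and 5 WT-only regions. LEF1, a transcription factor gene of the Wnt pathway, had 3 WT-only regions with −log10 q of at most 3.65 and none in K206R.

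Glycolysis and lactate genes had 51 shared, 9 WT-only and 2 K206R-only regions, a balance of −11.3% at percentile 57.5. ENO1, the enolase 1 gene, had a WT-only peak at chromosome 1 (8873853 to 8874239) with a pileup of 79 and a −log10 q of 19.6; the peak at its main start was listed in both libraries under ENO1-AS1. SLC16A1, which encodes the lactate transporter MCT1, had 2 WT-only and 1 K206R-only region, and the glucose transporter gene SLC2A1 had 5 shared and 2 WT-only regions. Hypoxia response genes had 57 shared, 13 WT-only and 4 K206R-only regions, a balance of −12.2% at percentile 54.5, and NDRG1 had 5, 2 and 1 of these. Lactylation and acylation enzymes had 25 shared, 4 WT-only and 2 K206R-only regions, a balance of −6.45% at percentile 68.4. The acetyltransferase gene CREBBP had 2 shared and 2 WT-only regions, and KAT8 had 1 shared and 1 K206R-only region. Super-enhancer machinery and coactivators had 34 shared, 11 WT-only and 6 K206R-only regions, a balance of −9.80% at percentile 65.0. The bromodomain gene BRD2 had 1 shared, 1 WT-only and 2 K206R-only regions.

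Genes of colon epithelial differentiation had 56 shared, 16 WT-only and 7 K206R-only regions, a balance of −11.4% at percentile 70.3. KLF4 had 13 shared, 4 WT-only and 3 K206R-only regions, and KLF5 had 7 shared and 3 WT-only regions. Cell cycle genes had 47 shared, 12 WT-only and 3 K206R-only regions, a balance of −14.5% at percentile 38.1, and CDK6 had 8, 4 and 1 of these. Genes used in nearly all cells had 48 shared, 12 WT-only and 4 K206R-only regions, a balance of −12.5% at percentile 57.5. Among them TUBB had 3 WT-only regions and none in K206R, and TFRC had 3 shared and 2 K206R-only regions. Endothelial markers had 41 shared, 11 WT-only and 5 K206R-only regions (percentile 71.5), stromal markers 16, 4 and 0 (percentile 23.3) and immune markers 7, 4 and 2 (percentile 33.5). Their balances were −10.5%, −20% and −15.4%. Immune markers were counted over 8 of the 18 listed genes and stromal markers over 8 of 16. The balance was −13.7% over all regions and −12.9% over coding genes. None of the 16 lists lay outside the central 95% of its random lists, where chance gives 0.8. Only a large loss of regions was simulated, so smaller shifts of these lists are not excluded. With equal numbers of peaks, which bring the balance over coding genes to −0.333% by construction, the lists lay between −15% and 9.09% and again none was outside. With a −log10 q of at least 5 in both libraries 3 lists did: glycolysis and lactate at percentile 98.4, ubiquitously used genes at 97.5 and immune markers, with 8 regions, at 0.18.

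**Figure D4:**
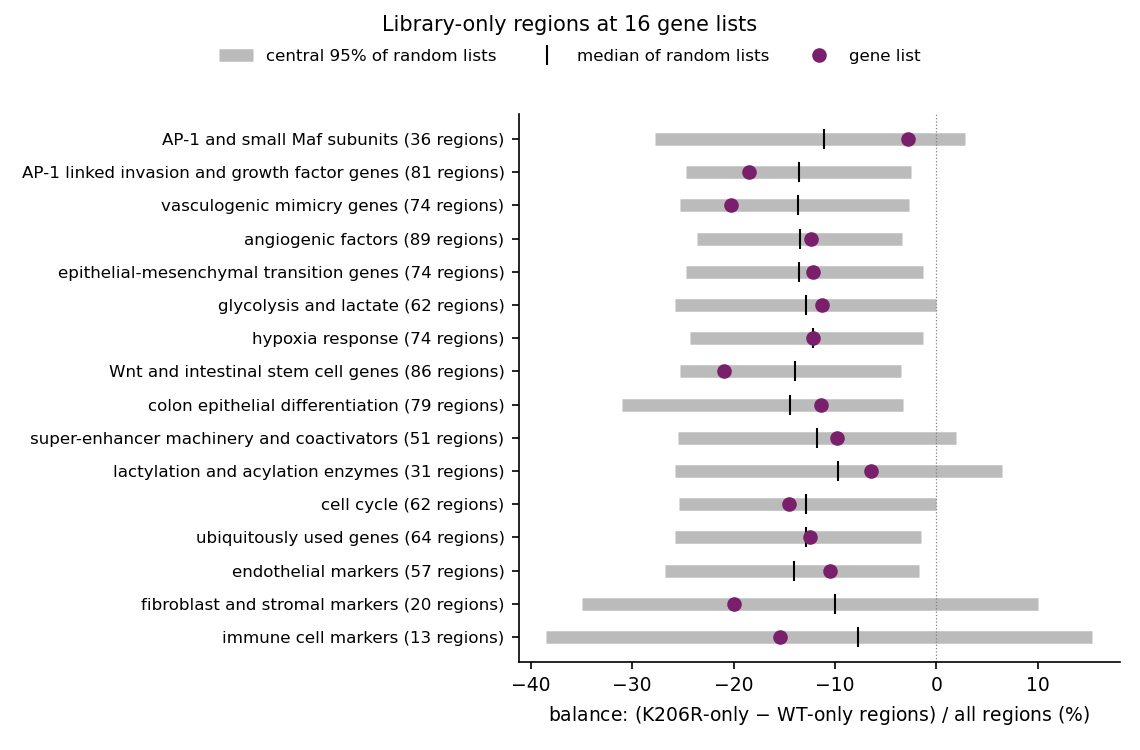
Balance of library-only regions, K206R-only minus WT-only as a share of all regions (%), for the 16 gene lists (points), with the median (ticks) and the central 95% (bars) of 10000 matched random lists. Every point lies within its bar, from −20.9% for Wnt and intestinal stem cell genes to −2.78% for AP-1 and small Maf subunits.

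Clusters of at least 5 peaks numbered 1353 in WT and 961 in K206R. They held 17.2% of the WT and 13.3% of the K206R peaks, with a median span of 34.9 kb in WT and 34.4 kb in K206R. Of the 1353 WT clusters, 2 contained no K206R peak, and of the 961 K206R clusters, 0 contained no WT peak. With equal numbers of peaks per library the WT library had 995 clusters. The genes with the most WT-only regions were EMBP1 with 131, EMB with 89, LOC101927293 with 87, LINC02167 with 79, LOC102724904 with 78 and LOC644669 with 68. The genes with the most K206R-only regions included EMBP1 with 39, EMB with 34, LOC102724904 with 31, and LOC101929373 and LOC105372345 with 21 each. These are nearest genes over long distances: the median distance of the regions from the start was 2223 kb at EMBP1 and 1401 kb at EMB.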

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

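The alternatives that thinned the WT library or left out peaks more than 500 kb from a start were chosen after seeing the data; the others were planned. Without replicates, values are set against their counting interval, which is narrow at these numbers, so most shares count as moved; the causes were not tested. No paired analysis was possible because each genotype had 1 library; for the same reason none was left out in turn. The AP-1 motif share and both of its alternatives were not run, since no genome sequence was used here. Peaks listed on few fragments carry the largest counting error; of 10 groups of WT peaks by rank, the lowest was shared in 24.0%.

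The share of WT and K206R peaks with a partner was 75.8% and 94.6% with a −log10 q of at least 5 in both libraries, 86.6% and 97.2% with it in the first list only, 85.1% and 85.5% with equal numbers of peaks, 70.9% and 82.9% with a reciprocal 50% overlap, and 72.7% and 88.1% with 50% of the peak covered. It was 83.3% and 85.0% after thinning WT to the K206R depth with a smallest length, and 78.0% and 90.6% without the distant peaks. The K206R share was the higher in all of these; with equal numbers of peaks both shares are close by construction. The Jaccard index was 0.676 with the stricter q and 0.683 with equal numbers.

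The promoter share of all WT and all K206R peaks was 42.6% and 48.1% with the stricter q and 31.2% and 34.8% within 1 kb of the start; for WT it was 41.5% after thinning. In WT-only and K206R-only peaks it was 20.4% and 22.1% with the stricter q and 10.0% and 10.8% within 1 kb.

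Genes with a library-only promoter peak numbered 1365 in WT and 1371 in K206R with equal numbers of peaks, 1529 and 1407 after thinning, 1190 and 219 with the stricter q in the first list only, and 1275 and 512 within 1 kb. In K206R they numbered 452 with the stricter q in both libraries and 1833 with the reciprocal overlap. Of the gene lists, 3 instead of 0 lay outside the random range with the stricter q. Clusters numbered 156 in WT and 54 in K206R with stitching within 5 kb, and 194 and 105 with at least 10 peaks. The other 31 settings of these results, among them all those of the FOSL1 locus, stayed within their interval or within 1.5 times the count.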

Other observations

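The tests of enrichment at shared peaks and of a uniform change of pileup, the thinning with a smallest length, and the comparisons by peak length and of pileups at single regions were chosen after the results were seen; the tests of depth, peak height and genotype were written before.

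At the regions listed in both libraries, a comparison of pileups adds to the presence or absence of peaks. Over 43917 pairs of shared peaks the median WT pileup was 1.39 times the K206R pileup, and each region's ratio of WT to K206R was divided by this median. Peaks that were split in 1 library and merged in the other were left out of the search for single regions, which kept 43345 pairs with a median ratio of 1.39 (1.39 to 1.40). On the K206R side stood the promoter of CKB, a creatine kinase gene, with a ratio of 0.538 (0.398 to 0.724). An intron of EPC1 had pileups of 14 in WT and 31 in K206R and a ratio of 0.324 (0.159 to 0.627). On the WT side stood the CEP112 promoter with 53 and 12 and a ratio of 3.17 (1.67 to 6.51), an intron of MAN1A1 with 85 and 24 and a ratio of 2.54 (1.60 to 4.18), and an intron of ATXN1 with 116 and 36 and a ratio of 2.31 (1.58 to 3.46). These regions were picked from the 15 pairs per side whose interval limit nearest to 1 lay furthest from it, out of those at coding genes, so chance extremes are not excluded. The interval missed the median ratio in 4.38% of the 43345 pairs, 983 toward WT and 916 toward K206R, where counting error around 1 common ratio gave 3.76% in 20 simulations (3.41 to 4.03). At the start of FOSL1 the ratio was 0.732 (0.548 to 0.979), on the K206R side of the median but at percentile 10.4 of all pairs, and at its upstream peak it was 0.973 (0.680 to 1.40). At the start of PKM it was 1.22 (0.975 to 1.53).

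The gene lists were also compared by the median of this ratio on the log2 scale. Ubiquitously used genes stood at −0.12, with 13 of 19 genes on the K206R side, at percentile 2.15 of random lists matched on pileup, and at 2.25 without the split peaks. None of the other 15 lists left the central 95%, and chance gives 0.8 lists of 16. The AP-1 and small Maf subunits stood at 0.00, at percentile 46.6, with 7 of 15 genes on the WT side. Angiogenic factors stood at 0.09 (percentile 92.1) and vasculogenic mimicry genes at 0.01 (percentile 74.1). Hypoxia response genes stood at −0.06 (percentile 15.2) and glycolysis and lactate genes at −0.08 (percentile 10.0).

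At similar summit pileup, short peaks were shared less often than long ones, more so in WT than in K206R. Fold and background were not held fixed in this comparison. Of WT peaks with a pileup above 40 and up to 60, 41.0% (34.0 to 48.5) of the 173 of at most 350 bp had a partner, against 99.5% of the 2136 above 1000 bp. In K206R these shares were 88.1% of 109 and 100% of 2554. Without peaks more than 500 kb from a start, the short WT peaks were shared in 36.8%. The peaks more than 500 kb from a start made up 4.45% of the WT list and 3.40% of the K206R list, with partners in 51.0% and 78.4%. EMBP1 and EMB, the genes given to many of them, lie next to the centromeric parts of chromosomes 1 and 5.

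The WT library listed 8339 more peaks than the K206R library. For a difference in sequencing depth, WT summits were thinned by the floor ratio of 1.27; 56034 peaks still passed the K206R p limit, above the 49104 of K206R, which had been set in advance as the outcome against depth. That bound was wrong in leaving out the smallest length of a listed peak, 275 and 276 bp. The WT-only peaks had a median length of 436 bp against 831 bp for shared ones. With this length and an assumed triangular profile depth alone left 49894 peaks (SD of the draws 60.8), still 790 above K206R. An assumed profile excludes nothing, so these counts do not decide on depth. Depth alone would give shared peaks a pileup ratio near the floor ratio of 1.27, and their median ratio was 1.39 (1.39 to 1.40). As far as the floor measures depth, this argues against depth as the only difference between these 2 libraries. How much of the surplus of WT peaks depth accounts for stays open. Weaker enrichment over background in the K206R library is consistent with the pileup ratio at shared peaks of 1.39 (1.39 to 1.40), which lay above the floor ratio; thinning to both depth and enrichment with the smallest length left 46123 peaks, below the K206R number. The PKM2 genotype cannot be told apart from these, because there was 1 library per genotype.

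Promoter peaks were shared more often than other peaks, by 18.9 points in WT. Within 10 bins of equal summed pileup, the log2 ratio of WT to K206R was 0.0612 (0.0533 to 0.0753) higher at other regions than at promoters. The change of pileup at shared regions was therefore not exactly uniform. These bins leave out the WT-only peaks that make the gap. To exclude a uniform change as its cause, uniform thinning with the smallest length also had to give the smaller part of the gap. It gave 14.9 of the 18.9 points, so a nearly uniform change stays open as the cause of the gap. Peak height with depth and enrichment gave a gap of 3.93 points when summits alone were thinned, below the observed gap and set in advance as speaking against it. The same missing length made this thinned gap too low. With the length the gap was 14.9 points (SD of the draws 0.211), still below the observed 18.9 points. The same rule thus went against peak height as the whole cause. As the 14.9 points rest on an assumed profile, peak height could still account for the gap in part or whole. A part of the PKM2 genotype in it was not tested and stays open.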
